A study of Mus musculus with 12 samples.

How the data were processed

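Gene expression was measured in single cells of the hippocampus of 12 male mice aged 19 to 22 months, 3 mice in each of 4 groups. Per the labels each library came from 1 mouse and was made with 10x Genomics Single Cell 3' version 2 reagents and sequenced on a HiSeq4000. Per the design text the hippocampal cells were sorted before loading. The groups were Control, P301L (mice carrying human tau with the P301L mutation), TauPS2APP (tau P301L together with mutant presenilin 2 and mutant amyloid precursor protein) and TauPS2APP;Trem2ko (the same transgenes without a working Trem2 gene). Per the design text the Control group held 2 non-transgenic mice and 1 Trem2-knockout mouse without transgenes (Control 2), analysed together. Replicate numbers followed the order of deposition and only name the mice.

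The deposited tables of the 12 libraries held raw counts of unique molecular identifiers (UMIs) per gene and cell, without normalization. A deposited cell table held counts of UMIs and genes per cell, a cluster of each cell and the authors' name for each cluster. The submitters' processing notes name GSNAP version 2013-10-10, Seurat, and the GRCm38 and mm10 genome builds, without saying which step each served. The calling of cells, the counting of UMIs and the annotation release were not given in the sources used here. The tables held 52636 genes, of which 52403 had a symbol in the annotation used here, and genes without a symbol held 0.0973% of the UMIs. All 66002 cells of the cell table were found in the matrices. The sums of the matrices were 2.16% to 2.48% above the UMI totals of the cell table, depending on the mouse, while the numbers of genes per cell were equal.

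The 12 libraries held 200448124 UMIs in all and between 9778646 and 28192780 per mouse. The lowest cell had 1010 UMIs. Cells were assigned to classes from the authors' 31 clusters together with the authors' names, and for microglia also from their subclusters (1 to 6, within clusters 2, 5 and 16) and for perivascular macrophages from subcluster 7, and each cluster's name was checked against marker genes. Other clusters and subclusters that the authors named microglia, and 1 cluster named brain endothelium that was led by pericyte markers, were kept out of these classes. Microglia subclusters 5 and 6 were kept in, although their 10 leading genes held 1 and 2 neutrophil markers and 0 microglial markers. The authors name subcluster 5 IFN Response, and its leading genes were Cxcl13, Ifit3 and Ccl12. They name subcluster 6 Classically Activated, and its leading genes were Il1b and Cxcl2. Oligodendrocyte cluster 4 was kept in too, although its 10 leading genes held 1 marker of committed oligodendrocyte precursors. The 10 leading genes of microglia subclusters 2, 3 and 4 held no marker of any class. The same held for microglia clusters 5 and 16 and for oligodendrocyte clusters 0, 1, 8 and 18. For these the check neither bore out nor went against the authors' names. The 4 classes tested were microglia (11364 cells), astrocytes (2870), oligodendrocytes (29918) and endothelial cells (2616). UMIs were summed over the cells of a class in each mouse, with at least 20 cells required. The sums per mouse ran from 1328264 to 4268977 UMIs in microglia and from 66039 to 973473 in astrocytes. They ran from 3833236 to 12952047 in oligodendrocytes and from 136394 to 1004631 in endothelial cells. Intervals on the counts of a single mouse are 95% Poisson intervals and cover counting error only.

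Summed counts were tested in R 4.3.3 with edgeR 4.0.16. Low genes were removed with its default expression filter, library sizes were scaled with TMM (trimmed mean of M values), and 1 quasi-likelihood model with a mean per group was fitted to all 12 mice of a class. The comparisons were P301L with Control, TauPS2APP with Control, TauPS2APP with P301L, and TauPS2APP;Trem2ko with TauPS2APP. TauPS2APP;Trem2ko was set to be compared with Control for gene lists. Its gene test came from the same model, and only its counts are given. P-values were adjusted over all tested genes of a class and comparison with the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05. Standard errors (SE) of log2 fold changes were computed from the fold change and the F statistic. Levels are CPM as the cpm function of edgeR gives them, as means ± SD over the 3 mice of a group. Where a group held 0 UMIs of a gene, a lower limit of the fold change was computed from a floor of 3 counts over the group. Where a group held 1 to 3 UMIs the levels or counts are given in place of a fold change.

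Genes were named by a fixed rule. It took Trem2 in microglia, then the 6 called genes with the largest fold change among those with a mean of at least 20 CPM in the higher group and all mice of one group beyond all mice of the other. It then took the 3 genes with the smallest p and up to 3 members of each gene list with the smallest p. Other genes are described as chosen after their values were seen. The 16 lists were written down before the data were examined: homeostatic microglia, early and late disease-associated microglia, MHC class II, MHC class I, proliferation, interferon response, cholesterol synthesis, integrated stress response, immediate early genes, reactive astrocyte, homeostatic astrocyte, disease-associated oligodendrocyte, myelin, blood-brain barrier endothelium and endothelial inflammation. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, again with a correlation estimated from the data, and with fry, each adjusted over the lists of a class and comparison. Adjusted p-values printed beside a list are those with the estimated correlation, since many lists passed only with the preset one.

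Shares of cell classes were taken over all annotated cells of a mouse. The 6 mice with the amyloid transgenes (TauPS2APP and TauPS2APP;Trem2ko) were compared with the other 6 mice by a two-sided exact permutation test of the difference of means, adjusted over 4 classes. Cluster abundance was tested with edgeR on cell counts per cluster. Other computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

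The groups, comparisons, tests and the following alternatives were set before the data were examined. The alternatives set then were DESeq2 1.42.0, RLE (relative log expression) scaling, no filter on low genes, only the 6 mice compared, only cells with at least 1000 UMIs and under 10% mitochondrial UMIs, cells with 2 or more UMIs of the markers of another class left out, counts thinned to the smallest mouse, only 1 of the P301L mice (the other 2 have sample titles of a separate number range, and the spread then comes from the other groups), and each mouse left out in turn. For shares they were non-neuronal cells or immune cells as denominator, and log2 shares. The log2 scale was not applied to cluster abundance, which was fitted as counts. The filter on cells removed 9 of all cells and so hardly altered the data. Alternatives added after the data were seen were the range of cell numbers in the deposited cell names (3 ranges) as a term in the model, all cells carrying the authors' name of a class, microglia subcluster 6 left out, cells of knockout mice with 3 or more Trem2 UMIs left out, and genes at 10 or more times the level in microglia left out of other classes. A single value of each of these 2 minimums was tried.

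The gene test was tested on simulated data with the means and dispersions of each class. At a simulated log2 change of 1 it recovered 25.3% to 60.9% of changed genes, depending on the class and comparison, and at a log2 change of 2 it recovered 73.2% to 95.6%. False calls made up 1.68% to 8.27% of calls, and 0 called genes had the wrong sign. The simulated counts were independent between genes and held no effect of a range of cell numbers or of a deviating mouse. These rates therefore do not cover false calls from such a structure. The abundance test was simulated in 1 run per comparison with 4-fold changes of 2 clusters. It recovered 2 of 2 in 3 comparisons and 1 of 2 in P301L with Control, and it called 1 unchanged cluster in TauPS2APP with P301L. The simulated spread between mice was a chosen setting and not that of these data, so the recovery does not describe clusters that vary more. Neurons, vascular mural cells, ependymal cells and unnamed clusters were not tested for genes. Oligodendrocyte precursors and T cells were tested after the comparisons of the report and are given at its end. Defining genes of clusters were not tested between groups.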

Results

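Single-cell RNA was measured in sorted hippocampal cells of 12 old male mice, 3 in each of 4 groups. The groups were Control, P301L (human mutant tau), TauPS2APP (mutant tau with mutant presenilin 2 and amyloid precursor protein) and TauPS2APP;Trem2ko (the same transgenes without Trem2). Cells per mouse numbered 6700, 4917 and 5848 in Control, 3723, 9108 and 6976 in P301L, 5136, 3069 and 4563 in TauPS2APP, and 4235, 5124 and 6603 in TauPS2APP;Trem2ko. The total count per mouse ran from 9778646 to 28192780 UMIs, and the median per cell from 2164 to 3612. All errors of log2 fold changes below are SE, all levels are mean CPM ± SD, n = 3 mice per group, and adjusted p is the Benjamini-Hochberg value of the edgeR quasi-likelihood test. The deposited cell names fall into 3 ranges of cell numbers. The first range held all TauPS2APP mice with knockout mice 1 and 2, the second all Control mice with P301L mouse 1 and knockout mouse 3, and the third P301L mice 2 and 3. TauPS2APP and Control or P301L mice therefore share no range. Each comparison therefore also says which of its named genes lost their call with the range as a term of the model. Of 137 named calls lost in this way, 111 kept at least 0.667 of their reported log2 fold change, so a lost call is not by itself a smaller change. The term is estimated only from knockout mouse 3 against knockout mice 1 and 2, and from P301L mouse 1 against P301L mice 2 and 3. A value with the term therefore rests on these few mice, and a kept or lost call does not decide whether the range matters.

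Trem2 encodes a lipid-sensing receptor of microglia and is the gene removed in the knockout mice. Its Ensembl identifier is ENSMUSG00000023992, and it lies on chromosome 17 from 48346401 to 48354147 in GRCm38. In microglia Trem2 stood at 3347 and 3545 CPM in the 2 non-transgenic Control mice and at 45.4 (95% Poisson interval 34.8 to 58.3) in the knockout mouse of that group. The P301L mice had 3453, 3766 and 3740 CPM, and the TauPS2APP mice 5587, 5434 and 6685. The knockout mice of the TauPS2APP;Trem2ko group had 7.51 and 15.2 CPM in mice 2 and 3. The library labelled TauPS2APP;Trem2ko 1 had 600.03 CPM (559 to 643), which goes partly against its label. In that library 83.5% of microglia held no Trem2 UMI and 15.1% held 3 or more.

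**Figure D1:**
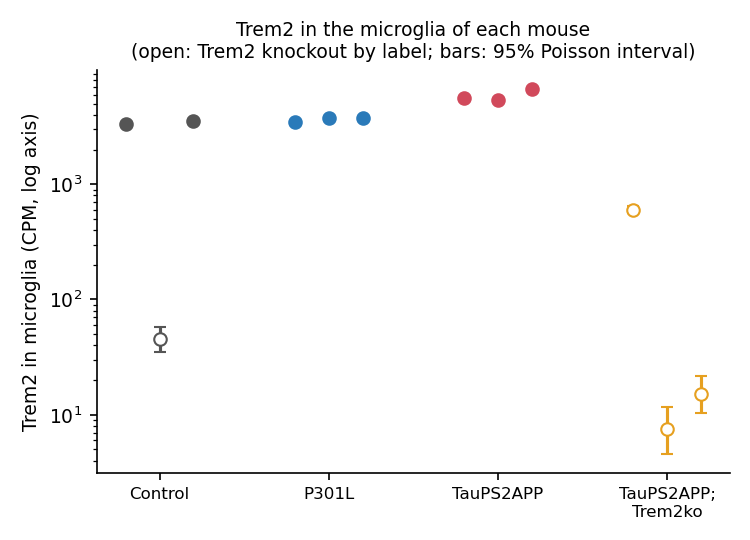
Trem2 level in microglia of each mouse on a log scale with 95% Poisson intervals. Open symbols are mice labelled as knockout.

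The question of P301L against Control is what mutant tau alone does to each cell class. In microglia Chst2, a sulfotransferase gene, rose by a log2 fold change of 2.31 ± 0.29 to 79.6 ± 9.0 CPM from 15.6 ± 3.63 (adjusted p = 0.00748), and its value with the range term was 2.42 (0.00949). Gcnt1, which encodes an enzyme of O-glycan branching, rose by 1.59 ± 0.17 (224 against 74.7 CPM, adjusted p = 0.00308). Rfk, encoding riboflavin kinase, rose by 1.73 ± 0.19 (70.8 against 21.5 CPM, adjusted p = 0.00308). Prune2 fell by 1.71 ± 0.27 (11.2 against 36.7 CPM, adjusted p = 0.0346), and it is a neighbour of both genes on chromosome 19. Fam20c, a secretory pathway kinase gene, rose by 2.03 ± 0.37 (adjusted p = 0.0489), and AB124611, a myeloid membrane protein gene, rose by 2.02 ± 0.34 (adjusted p = 0.0383). The lysosomal protease gene Ctsb rose by 0.74 ± 0.12 (adjusted p = 0.0357), the tetraspanin gene Cd63 by 1.30 ± 0.20 (adjusted p = 0.0317) and the protease inhibitor gene Timp2 by 0.80 ± 0.14 (adjusted p = 0.0406). Apoe, the lipid carrier gene, measured 22678 ± 5012 CPM against 5164 ± 4223 and did not pass (log2 fold change 2.13 ± 0.47, adjusted p = 0.0731).

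Of the 9 named calls of P301L microglia, 8 were lost with the range term and Chst2 alone kept its call. Gcnt1 (1.65) and Rfk (1.57) then had an adjusted p of 0.0987. Fam20c (1.90), Prune2 (-1.80), Ctsb (0.62) and Cd63 (1.01) had 0.724, AB124611 (1.72) had 0.747 and Timp2 (0.65) had 0.751. All 8 kept at least 0.667 of their reported change.

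In GRCm38 Prune2 (ENSMUSG00000039126) starts at 16956118 on chromosome 19, Gcnt1 (ENSMUSG00000038843) at 17326141, and Rfk (ENSMUSG00000024712) ends at 17401349. Prune2 stood at 36.7 CPM in Control, 11.2 in P301L, 41.4 in TauPS2APP and 29.9 in TauPS2APP;Trem2ko microglia, and Gcnt1 at 74.7, 224, 99.6 and 124. Rfk ranked these groups as Gcnt1 did in microglia, with 21.5, 70.8, 51.3 and 52.1 CPM. In oligodendrocytes of the same groups Rfk stood at 32.2, 64.7, 63.8 and 64.8 CPM, so P301L did not stand apart there.

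**Figure D2:**
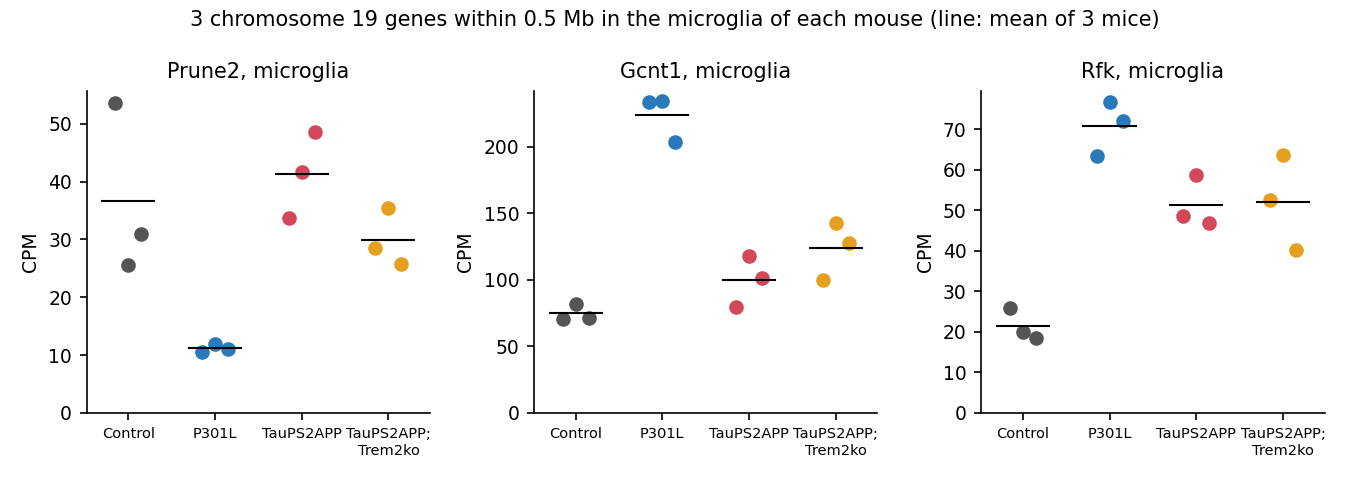
Levels of the neighbouring genes Prune2, Gcnt1 and Rfk in microglia of each mouse.

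In these microglia 25 of 12660 tested genes passed, 18 higher and 7 lower. Of the late disease-associated list (genes of Trem2-dependent plaque microglia) 2 of 24 rose, or 20 adjusted over the list alone, with a median log2 change of 1.37 (1.19 to 2.32 with 1 mouse left out, adjusted p = 0.0136 with an estimated correlation). Of the early list (Apoe, Tyrobp, cathepsins) 1 of 7 rose, or 7 adjusted over the list alone (median 0.74, adjusted p = 0.0186 with an estimated correlation). Homeostatic microglia genes had a median of -0.36, with 0 of 14 passing and 8 lower adjusted over the list alone (adjusted p = 0.111 with an estimated correlation). MHC class II genes, which present peptides to helper T cells, had a median of 3.07 (1.84 to 3.54 with 1 mouse left out) with 0 of 6 passing and 4 higher adjusted over the list alone (adjusted p = 0.111 with an estimated correlation). MHC class I genes had a median of 0.52 (0.27 to 0.62 with 1 mouse left out), with 0 of 12 passing and 4 higher adjusted over the list alone (adjusted p = 0.184 with an estimated correlation). The interferon response had a median of -0.61, with 0 of 18 passing and 1, against the median, higher adjusted over the list alone (adjusted p = 0.344 with an estimated correlation). Proliferation had a median of -0.17, or -1.46 to 0.28 with 1 mouse left out. It had 0 passing members, as did cholesterol synthesis (0.20, adjusted p = 0.213 with an estimated correlation), integrated stress response (-0.13) and immediate early genes (-0.21, 0.517). The number of passing genes was 80 without Control mouse 1, between 2 and 9 without any other mouse, 147 with DESeq2, and 1 with the range term. It was 0 with P301L mouse 1 only, a group of 1 mouse whose spread the model takes from the other groups.

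In astrocytes Serpina3n, a secreted protease inhibitor of reactive astrocytes, rose by 2.70 ± 0.31 in P301L mice (165 against 23.5 CPM, adjusted p = 1.8e-05). C4b, encoding complement factor 4, rose by 1.43 ± 0.22 (528 against 189 CPM, adjusted p = 0.00179), and the predicted gene Gm14328 fell by 2.07 ± 0.37 (18.0 against 75.8 CPM, adjusted p = 0.0152). With the range term Serpina3n measured 3.08 (adjusted p = 0.00184) and C4b 1.77 (adjusted p = 0.0051), while Gm14328 lost its call (-1.71, 0.743). These 3 genes were all that passed of 7440 in astrocytes. The count was 30 without Control mouse 3, 6 and 8 without P301L mice 1 and 3, 12 with P301L mouse 1 only, and 14 with the range term. Of the reactive astrocyte list 2 of 17 rose, or 9 with 1 lower adjusted over the list alone (median 0.89, adjusted p = 0.059 with an estimated correlation). The homeostatic astrocyte (0 of 15), cholesterol synthesis (0 of 15), integrated stress response (0 of 11), interferon (0 of 7), MHC class I (0 of 7) and immediate early (0 of 5) lists had no passing members.

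In oligodendrocytes Cdkn1a, the cell cycle inhibitor p21, rose by 4.11 ± 0.37 in P301L mice (101 ± 38.4 against 6.05 ± 3.12 CPM, adjusted p = 0.0011) and measured 4.57 with the range term (adjusted p = 0.00383). Steap3, an iron reductase gene, rose by 3.02 ± 0.30 (4.18 against 0.493 CPM, adjusted p = 0.00183), and Rfk rose by 1.01 ± 0.11 (64.7 against 32.2 CPM, adjusted p = 0.00479). Steap3 (3.2, 0.0526) and Rfk (1.09, 0.138) lost their calls with the range term at changes as large as before. In all 5 of 14899 genes passed, 4 higher and 1 lower. The count was 18 without Control mouse 1, 3 without P301L mouse 3 and 1 with the range term. Disease-associated oligodendrocyte genes had a median of 0.31 with 0 of 13 passing and 4 higher adjusted over the list alone (adjusted p = 0.133 with an estimated correlation), and 0 of 18 myelin genes passed. The interferon list had a median of -1.14 with 0 of 17 passing and 5 lower adjusted over the list alone (adjusted p = 0.424 with an estimated correlation). In endothelial cells 0 of 8175 genes passed with edgeR and 0 with DESeq2. An unadjusted p below 0.05 was found for 320 genes, fewer than the 409 due by chance. There the barrier (0 of 14) and inflammation (0 of 10) lists had no passing members. Leaving out Control mouse 2 or P301L mouse 3 gave 2 and 5 passing endothelial genes, P301L mouse 1 alone gave 5, and edgeR without the filter on low genes gave 66.

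TauPS2APP against Control asks what amyloid and tau transgenes together do. Microglia of TauPS2APP mice held 1036 UMIs of the Wnt inhibitor gene Dkk2 (95.1 ± 26.4 CPM) where Control microglia held 0, a rise of at least 240-fold against a floor of 3 counts (adjusted p = 1.9e-06). The transcription cofactor gene Cited4 had 268 UMIs against 0, at least 62.2-fold (24.8 CPM). Levels of the heparanase gene Hpse were 89.1 against 0.23 CPM, of the actin-binding gene Baiap2l2 119 against 0.467 (adjusted p = 7.0e-07) and of the secreted protein gene Lgi2 21.6 against 0.147. Gpnmb, a lysosomal glycoprotein gene, rose by 6.80 ± 1.02 to 474 ± 335 CPM (adjusted p = 5.1e-04). The phosphate transporter gene Ank rose by 3.86 ± 0.25 (adjusted p = 1.7e-06) and the growth factor gene Csf1 by 3.68 ± 0.31 (adjusted p = 7.5e-06). Genes of resting microglia fell: the surface protein gene Tmem119 by 1.73 ± 0.11 (734 against 2440 CPM, adjusted p = 1.7e-06) and the purinergic receptor gene P2ry12 by 1.61 ± 0.17 (982 against 2991 CPM, adjusted p = 4.5e-05). The ligand gene Selplg fell by 1.41 ± 0.13 and the adaptor gene Grap by 2.40 ± 0.15 (adjusted p = 1.7e-06). With the range term Ank (3.05, 0.00255), Tmem119 (-1.62, 0.0076), Csf1 (3.34, 0.0231), Dkk2, Baiap2l2, Grap, Selplg and P2ry12 kept their calls. Gpnmb (3.36, 0.547) lost its call at a much smaller value, and Lgi2 (0.352), Cited4 (0.0582) and Hpse (0.0512) lost theirs.

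All 24 late disease-associated genes rose in TauPS2APP microglia (median 3.16, adjusted p = 0.0093 with an estimated correlation), as did all 7 early genes (median 1.32, 0.0158), among them Ctsb (1.59), Tyrobp (1.32) and Ctsd (1.12). Of homeostatic genes 11 of 14 fell, or 12 adjusted over the list alone (median -0.85, 0.0158). MHC class II rose in 4 of 6 members, with H2-Aa at 5.89 ± 0.85 (748 against 12.8 CPM), Cd74 at 5.05 ± 0.83 and H2-Ab1 at 4.90 ± 0.82 (adjusted p = 0.226 with an estimated correlation for the list). MHC class I rose in 5 of 12 (6 adjusted over the list alone, median 0.78, adjusted p = 0.386 with an estimated correlation), including H2-D1 (1.72), H2-K1 (1.32) and B2m (1.16). Cholesterol synthesis rose in 5 of 14 (6 adjusted over the list alone, median 0.55, adjusted p = 0.0683 with an estimated correlation), including the sterol desaturase gene Sc5d (1.01) and Insig1 (2.02), which regulates sterol synthesis. Immediate early genes rose in 9 of 15 (12 adjusted over the list alone, median 1.19, adjusted p = 0.370 with an estimated correlation), with Atf3 at 1.84, Zfp36 at 1.06 and Fos at 1.44. The interferon list had 3 of 18 higher, Lgals3bp (1.54), Ifi27l2a (1.46) and Oasl2 (1.20), with a median of -0.09 and a mean of 0.02. In the stress response 2 rose (Psat1 1.59, Sdf2l1 0.92) and 3 fell of 12, Xbp1 by 0.72. Proliferation had 0 of 9 passing members (median -0.71, or -0.92 to -0.26 with 1 mouse left out).

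Of the list members named for TauPS2APP microglia against Control, Ctsb, H2-Aa, Cd74, H2-Ab1, Lgals3bp and Psat1 kept their calls with the range term. The immediate early genes Atf3 (0.57, adjusted p = 0.644), Zfp36 (0.47, 0.621) and Fos (0.43, 0.725) lost theirs with much smaller values. So did Sc5d (0.66, 0.365) and Insig1 (1.15, 0.579). The calls of Xbp1 (-0.60, 0.381), Tyrobp (1.28, 0.062) and Ctsd (0.94, 0.133) were lost at similar values. Those of H2-D1 (2.10, 0.0525), B2m (1.38, 0.122), H2-K1 (1.88, 0.078), Ifi27l2a (2.3, 0.0955), Oasl2 (1.43, 0.265) and Sdf2l1 (1.2, 0.0831) were lost at larger ones.

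In all 2208 of the 12660 microglial genes passed, 1282 higher and 926 lower. The count was 1209 without Control mouse 3, 1392 without TauPS2APP mouse 2, 1450 without TauPS2APP mouse 3, and 124 with the range term. Within the second range, knockout mouse 3 against P301L mouse 1 gave a median of 0.02 for the 1282 higher genes and -0.03 for the 926 lower genes. This is 1 mouse against 1, and neither belongs to TauPS2APP or Control. The late disease-associated median against Control was 1.31 in the knockout group and 1.37 in P301L. A value near 0 therefore cannot tell an effect of the range from similar changes in these 2 groups. Subcluster 1 of the authors, named Resting/Homeostatic, held 86.6% of Control, 66.0% of P301L, 20.3% of TauPS2APP and 36.0% of TauPS2APP;Trem2ko microglia. Subcluster 3, named DAM1, held 9.89%, 28.8%, 50.2% and 26.7%. The knockout mice held 22.1%, 47.5% and 38.5% in subcluster 1. The authors also give the name Resting/Homeostatic to subcluster 2, which was led by mitochondrial transfer RNA genes. Subcluster 2 held 39.6% of the microglia of knockout mouse 1 and 1.56% and 1.87% of those of mice 2 and 3. Its means were 0.0876% in Control, 0.370% in P301L, 1.41% in TauPS2APP and 14.3% in TauPS2APP;Trem2ko. Subcluster 1 alone is therefore not the whole share under that name, least of all in knockout mouse 1. Subcluster 4, named DAM2, held 24.3% of TauPS2APP microglia and 0.343% of knockout microglia. Perivascular macrophage markers rose in these microglia (2 of 2, median 2.88). Mixed clusters kept out of the class held 2.49%, 3.47%, 2.68% and 2.51% of all cells in the 4 groups, with 1.10%, 6.91% and 2.41% in the 3 P301L mice.

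**Figure D3:**
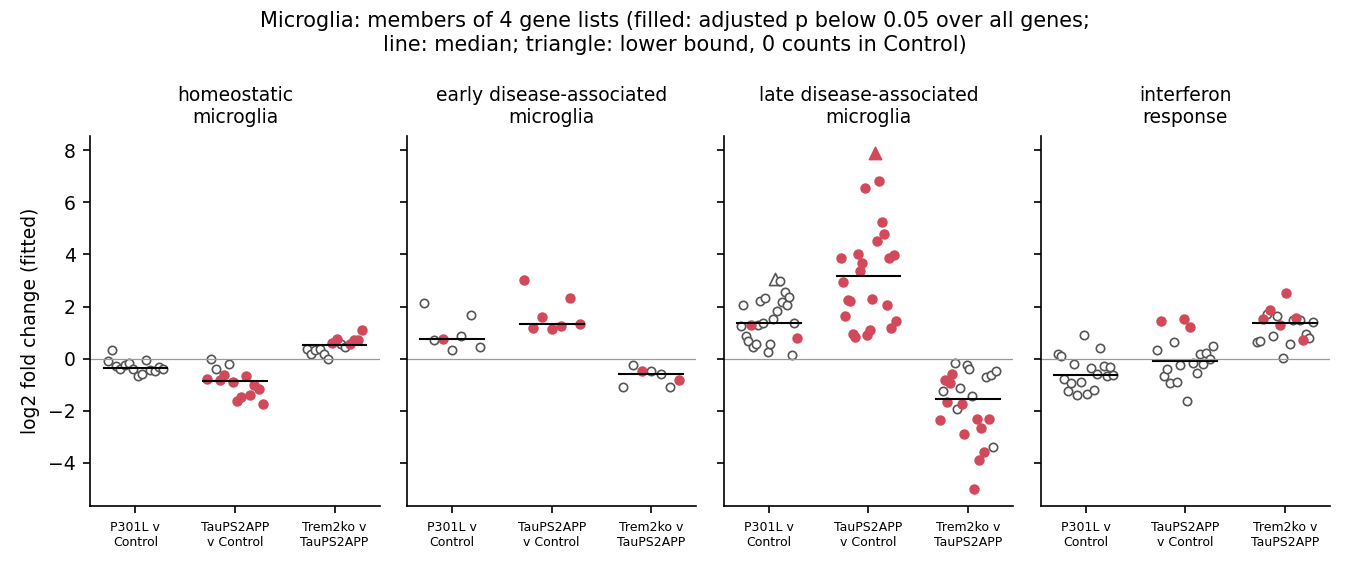
Log2 fold changes of the members of 4 gene lists in microglia in 3 comparisons. Filled points have an adjusted p below 0.05, lines are medians, and triangles are lower limits for genes with 0 Control UMIs.

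Astrocytes of TauPS2APP mice raised Serpina3n by 4.13 ± 0.32 over Control (417 against 23.5 CPM, adjusted p = 1.6e-09), C4b by 2.15 ± 0.23 (848 against 189 CPM, adjusted p = 7.1e-07) and the filament gene Gfap by 2.06 ± 0.27 (3443 against 824 CPM, adjusted p = 3.0e-05). The protease inhibitor gene A2m rose by 4.65 ± 0.61 (136 against 5.11 CPM, adjusted p = 3.0e-05), and the sphingosine receptor gene S1pr3 stood at 55.0 against 1.49 CPM. With the range term Serpina3n measured 4.29 (adjusted p = 5.7e-06), Gfap 2.84 (1.4e-04) and C4b 2.06 (0.00751), and S1pr3, Ifitm3, B2m, Cst7 and Cd74 also kept their calls. A2m (3.30, 0.159), H2-D1 (1.66, 0.203) and Tyrobp (2.14, 0.0979) lost theirs, and Gm49369 reversed to -1.43. Of the reactive list 8 of 17 rose, or 13 with 1 lower adjusted over the list alone (median 1.83, adjusted p = 0.0039 with an estimated correlation). MHC class I rose in 2 of 7, H2-D1 (1.23) and B2m (0.93), and 3 adjusted over the list alone (median 0.87, adjusted p = 0.0316 with an estimated correlation). The interferon list had 1 of 7 higher, Ifitm3 (1.49), and 3 adjusted over the list alone (median 1.28, 0.0406). Cholesterol synthesis had a median of -0.62, with 0 of 15 passing and 5 lower adjusted over the list alone (adjusted p = 0.0316 with an estimated correlation). Homeostatic astrocyte (0 of 15), stress response (0 of 11) and immediate early genes (0 of 5, 2 higher adjusted over the list alone, adjusted p = 0.0974 with an estimated correlation) had no passing members. Of the 39 genes that passed (35 higher, 4 lower), 12 were at 10 or more times the level in microglia, among them Cst7 (132 against 0 CPM), Tyrobp, Cd74 and the predicted gene Gm49369. Microglial markers had a median of 0.86 in this class. The count was 23 without Control mouse 1, 20 without TauPS2APP mouse 3 and 14 with the range term. The smallest astrocyte sample was knockout mouse 1 with 49 cells.

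In oligodendrocytes of TauPS2APP mice Cdkn1a rose by 7.06 ± 0.40 (779 ± 80.7 against 6.05 ± 3.12 CPM, adjusted p = 5.1e-06), with 7.21 under the range term (3.6e-04). The cyclin gene Ccnd1 rose by 3.73 ± 0.22 (84.5 against 6.42 CPM, adjusted p = 5.1e-06; 3.89 under the range term, 0.00115) and the synaptotagmin gene Syt4 by 6.44 ± 0.42 (115 against 1.31 CPM, adjusted p = 6.4e-06). Of disease-associated oligodendrocyte genes 6 of 13 rose and 1 fell, or 6 and 2 adjusted over the list alone (median 0.68, adjusted p = 0.146 with an estimated correlation). The filament gene Vim rose by 2.49 ± 0.30, C4b by 1.85 ± 0.25 (532 against 147 CPM, adjusted p = 7.9e-04) and Serpina3n by 2.27 ± 0.42 (405 against 83.7 CPM, adjusted p = 0.00618). Under the range term C4b measured 1.34 (0.25), Serpina3n 2.35 (0.255) and Vim 2.61 (0.0549). Myelin genes fell in 7 of 18, or 8 adjusted over the list alone (median -0.32, adjusted p = 0.146 with an estimated correlation, 0.0089 with fry). Among them were the lipid enzyme genes Fa2h (-0.53) and Ugt8a (-0.50) and the myelin enzyme gene Cnp (-0.52 ± 0.11, 4366 against 6256 CPM, adjusted p = 0.0163). With the range term Cnp lost its call at a similar value (-0.43, 0.383). MHC class I rose in 3 of 12, H2-D1 (2.12), B2m (2.14) and H2-K1 (1.46), and 5 adjusted over the list alone (median 1.05, or 0.63 to 1.36 with 1 mouse left out, adjusted p = 0.272 with an estimated correlation). In the stress response 4 rose and 1 fell of 13 (median -0.14, mean 0.26), with the transcription factor genes Nupr1 (1.69) and Ddit3 (1.21) higher and Psat1 (-0.63) lower. Immediate early genes rose in 4 of 16 (7 adjusted over the list alone, median 0.61, adjusted p = 0.220 with an estimated correlation), with Atf3 at 2.22, Egr1 at 2.13 and Fos at 1.98. The interferon list had Lgals3bp higher (2.40) and Ifi27l2a lower (-2.07) of 17. Cholesterol synthesis had 1 of 18 lower, Dhcr7 (-0.74), and 3 adjusted over the list alone (median -0.33, adjusted p = 0.220 with an estimated correlation). Of these list members Nupr1 and Ddit3 kept their calls with the range term. The calls of Fa2h (-0.66, 0.148), Ugt8a (-0.80, 0.0822), H2-D1 (2.52, 0.0995), B2m (2.90, 0.0514), H2-K1 (2.45, 0.071), Atf3 (2.27, 0.0639), Lgals3bp (3.19, 0.0514) and Dhcr7 (-1.03, 0.0953) were lost at larger values. Those of Psat1 (-0.44, 0.367), Egr1 (1.67, 0.374), Fos (1.73, 0.31) and Ifi27l2a (-0.56, 0.813) were lost at smaller ones. Microglial markers had a median of 0.71 with 2 of 7 higher in these oligodendrocytes, and T cell markers 2.46 with 1 of 2 higher.

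In all 1047 of 14899 oligodendrocyte genes passed, 591 higher and 456 lower, and 100 of them were at 10 or more times the level in microglia. The count was 566 without Control mouse 1, 681 without Control mouse 2, 577 and 554 without TauPS2APP mice 2 and 3, and 105 with the range term. Within the second range, knockout mouse 3 against P301L mouse 1 gave a median of 0.72 for the higher genes (93.7% in the same direction) and -0.50 for the lower genes (96.5%). This too is 1 mouse against 1, and neither belongs to TauPS2APP or Control. The authors' cluster 0 held 69.6% of Control, 50.7% of P301L, 14.2% of TauPS2APP and 8.74% of knockout oligodendrocytes, and cluster 1 held 3.52%, 19.9%, 61.7% and 59.1%. Cluster 4 held 25.5%, 27.6%, 11.4% and 7.19%. Cluster 8, led by Syt4, Cdkn1a and other genes including Ddit3, held 0.0171%, 0.624%, 11.9% and 20.6%. Cdkn1a was among the 10 leading genes of cluster 1 as well. In endothelial cells 21 of 8175 genes passed, of which 10 were at 10 or more times the level in microglia, among them Cst7, Spp1, Trem2, Tyrobp and Ly86. The leucine-rich glycoprotein gene Lrg1, a marker of inflamed endothelium, rose by 4.24 ± 0.86 (145 ± 197 against 7.85 ± 9.53 CPM, adjusted p = 0.0479) without separating the groups. The readthrough gene Gm21984 fell by 2.11 ± 0.30 (adjusted p = 0.0026). Endothelial inflammation had 1 of 10 higher and 8 adjusted over the list alone (median 1.23, or 0.69 to 1.74 with 1 mouse left out, adjusted p = 0.117 with an estimated correlation), barrier genes 0 of 14 (median 0.03), and MHC class I 0 of 11 with 5 adjusted over the list alone (median 0.54, or 0.29 to 0.73 with 1 mouse left out, adjusted p = 0.176 with an estimated correlation). The endothelial count was 11 and 10 without Control mice 2 and 3, 5 without TauPS2APP mouse 3, and 1 with the range term, where Tyrobp alone of the named genes kept its call and Lrg1 measured 5.57 (0.775). Microglial markers had a median of 0.886 in this class, with 2 of 7 higher.

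**Figure D4:**
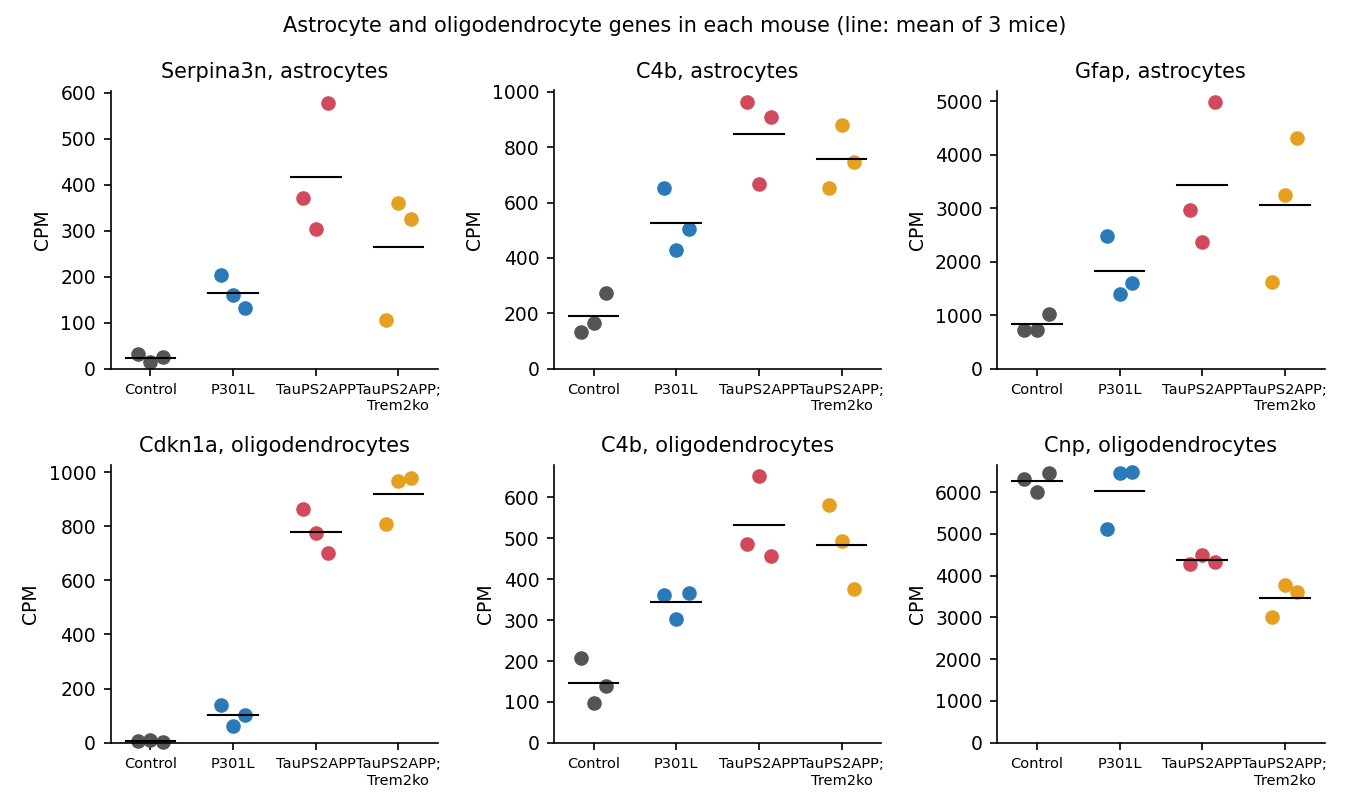
Levels of Serpina3n, C4b and Gfap in astrocytes and of Cdkn1a, C4b and Cnp in oligodendrocytes of each mouse. Lines are means of 3 mice.

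TauPS2APP against P301L asks what the amyloid transgenes add to tau. In microglia Cst7, a cystatin gene of plaque microglia, rose by 4.24 ± 0.51 (4599 against 243 CPM, adjusted p = 4.7e-04). Dkk2 rose by 4.82 ± 0.34 (95.1 against 3.13 CPM, adjusted p = 2.5e-05), Baiap2l2 by 5.14 ± 0.32 (adjusted p = 2.0e-06), Hpse by 5.19 ± 0.67 and the predicted gene Gm13889 by 3.75 ± 0.23 (adjusted p = 2.0e-06). Cited4 had 268 UMIs against 2 and Lgi2 had 231 against 2. The ankyrin repeat gene Asb10 rose by 2.46 ± 0.20. Tmem119 fell by 1.32 ± 0.11 (adjusted p = 3.2e-05; -1.18 with the range term, 0.33), Selplg by 0.98 and the matrix gene Sparc by 0.83. In all 943 of 12660 genes passed, 568 higher and 375 lower. The count was 310 and 322 without P301L mice 2 and 3, 416 and 397 without TauPS2APP mice 2 and 3, 29 with P301L mouse 1 only and 0 with the range term, so that each of the 28 named microglial calls over P301L was lost with that term. Of these, 22 kept at least 0.667 of their change, such as Cst7 (4.55, 0.355), Dkk2 (5.05, 0.491) and Baiap2l2 (6.14, 0.0851), while Atf3 (0.58, 0.815), Zfp36 (0.67, 0.719) and Insig1 (1.01, 0.809) were among those that did not.

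Of the late disease-associated genes 16 of 24 rose over P301L (21 adjusted over the list alone, median 1.32, adjusted p = 0.0401 with an estimated correlation), and 9 of 14 homeostatic genes fell (11 adjusted over the list alone, median -0.59, 0.0401). Early genes rose in 3 of 7 (Ctsb 0.86, Tyrobp 0.87, Ctsd 0.79; adjusted p = 0.159 with an estimated correlation) and immediate early genes in 9 of 15 (13 adjusted over the list alone, median 1.27, adjusted p = 0.159 with an estimated correlation), with Atf3 at 1.98. MHC class II had 1 of 6 higher, H2-Aa (2.43 ± 0.68, adjusted p = 0.0464), and 3 adjusted over the list alone (adjusted p = 0.532 with an estimated correlation). Cholesterol synthesis had 3 of 14 higher, Insig1 (1.86), Sc5d (0.69) and Sqle (1.45). Its median was 0.29, or 0.26 to 0.60 with 1 mouse left out (adjusted p = 0.201 with an estimated correlation). The interferon list had 2 of 18 higher, Oasl2 (1.54) and Ifi27l2a (1.37), and 4 adjusted over the list alone (adjusted p = 0.532 with an estimated correlation). In the stress response Psat1 (1.82) and Sdf2l1 (0.67) rose and Herpud1 fell by 0.69. MHC class I (0 of 12, median 0.13) and proliferation (0 of 9, median -0.19, with the test pointing up) had no passing members.

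In astrocytes Serpina3n rose by 1.42 ± 0.27 over P301L (417 against 165 CPM, adjusted p = 0.00581; 1.21 with the range term, 0.94), and the predicted gene Gm13339 by 2.02 ± 0.36. Of 14 passing genes, all higher, 9 were at 10 or more times the level in microglia, such as Cst7, Trem2, Tyrobp, Lyz2 and C1qb. The reactive list had 1 of 17 higher and 8 adjusted over the list alone (median 0.72, or 0.41 to 1.06 with 1 mouse left out, adjusted p = 0.114 with an estimated correlation), and the interferon, MHC class I and cholesterol lists had 0. The count was 25 without P301L mouse 1, 8 without P301L mouse 3, 5 without TauPS2APP mouse 2 and 1 with the range term. In oligodendrocytes Syt4 rose by 4.46 ± 0.34, the transcription factor gene Sox4 by 2.67 ± 0.19 (22.8 against 3.54 CPM, adjusted p = 3.3e-05), the growth factor gene Fgf7 by 3.23 ± 0.29 and Vim by 1.60 ± 0.28. Myelin genes fell in 3 of 18, Fa2h (-0.49), Mobp (-0.42) and Cnp (-0.46), and 9 fell adjusted over the list alone (median -0.28, adjusted p = 0.263 with an estimated correlation). Disease-associated oligodendrocyte genes had 2 of 13 higher, MHC class I 1 of 12 (B2m 1.49; adjusted p = 0.511 with an estimated correlation), interferon 2 of 17 (Lgals3bp 1.99, Trim30a 2.14) and immediate early 3 of 16, while Dhcr7 of cholesterol synthesis fell by 0.62. In the stress response Nupr1 (1.22) and Ddit3 (0.82) rose and Psat1 fell by 0.54. In all 520 oligodendrocyte genes passed, 331 higher and 189 lower, and 93 of them were at 10 or more times the level in microglia. Microglial markers rose in 4 of 7 in these oligodendrocytes (median 1.06). This count was 305, 182 and 166 without P301L mice 1, 2 and 3, 180 and 183 without TauPS2APP mice 2 and 3, 5 with P301L mouse 1 only and 0 with the range term. In endothelial cells 9 genes passed, 7 higher and 2 lower. The inflamed vessel gene Tmem252 rose by 1.86 ± 0.32 (669 against 187 CPM, adjusted p = 0.025), Gm21984 fell by 1.81 ± 0.31, and 6 of the 9 were at 10 or more times the level in microglia. The inflammation list had 1 of 10 higher and 3 adjusted over the list alone (median 0.85, or 0.24 to 1.40 with 1 mouse left out, adjusted p = 0.295 with an estimated correlation), and barrier genes 0 of 14 (-0.07). The endothelial count was 5 and 3 without TauPS2APP mice 2 and 3. Each named call of oligodendrocytes and endothelial cells over P301L was lost with the range term, although 15 of 22 in oligodendrocytes, such as Sox4 (2.96, 0.105), and 7 of 7 in endothelial cells kept at least 0.667 of their change. The astrocyte calls of Gm13339 (1.01) and the microglial genes were lost too.

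TauPS2APP;Trem2ko against TauPS2APP asks which of these levels depend on Trem2. Among microglia Dkk2 fell by 5.01 ± 0.36 (3.27 against 95.1 CPM, adjusted p = 7.1e-05; -4.88 with the range term, 0.00312). The lysosomal proton pump gene Atp6v0d2 fell by 4.98 ± 0.61 (2.13 against 55.5 CPM, adjusted p = 0.00123), the integrin gene Itgax by 3.58 ± 0.44 (20 against 229 CPM, adjusted p = 0.00123) and Gpnmb by 3.89 ± 0.83 (35.3 against 474 CPM, adjusted p = 0.0246). Cited4 fell by 4.0 ± 0.49, the scavenger receptor gene Colec12 by 3.65 ± 0.84, Gm13889 by 2.47 ± 0.21 and Ank by 2.35 ± 0.23. Grap rose by 1.79 ± 0.15 (143 against 41.6 CPM, adjusted p = 7.1e-05) and Tmem119 by 1.08 ± 0.11 (1555 against 734 CPM, adjusted p = 2.8e-04), as did Sparc (0.74) and the lectin gene Siglech (0.72). Gpnmb (-3.33, 0.0955) and Colec12 (-3.02, 0.13) lost their calls with the range term at similar values, and the others named so far kept theirs. Trem2 itself measured -5.04 ± 1.44 with an adjusted p of 0.0762 and the levels per mouse given above.

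Of late disease-associated genes 13 of 24 fell without Trem2 (21 adjusted over the list alone, median -1.54, adjusted p = 0.0396 with an estimated correlation). Early genes fell in 2 of 7, Tyrobp (-0.80) and Ctsb (-0.48), and in 6 adjusted over the list alone (median -0.57, adjusted p = 0.105 with an estimated correlation). Without the cells that hold markers of another class Ctsb measured 0.14. Homeostatic genes rose in 6 of 14, or 10 adjusted over the list alone (median 0.51, adjusted p = 0.0539 with an estimated correlation). Interferon response genes rose in 6 of 18, or 15 adjusted over the list alone (median 1.37, or 0.90 to 1.58 with 1 mouse left out, adjusted p = 0.0823 with an estimated correlation), with Ifit3 at 1.85 ± 0.37 (71.1 against 20.2 CPM), Mx1 at 2.53 ± 0.52 and Trim30a at 0.73. Cholesterol synthesis fell in 3 of 14, Sc5d (-0.92), Msmo1 (-0.78) and Insig1 (-1.60), or 6 adjusted over the list alone (median -0.68, adjusted p = 0.0539 with an estimated correlation). MHC class II had 0 of 6 passing (1 lower adjusted over the list alone, median -1.31, or -2.88 to -0.89 with 1 mouse left out, adjusted p = 0.438 with an estimated correlation), MHC class I 0 of 12 (0.11), the stress response 0 of 12 (0.20) and immediate early genes 0 of 15 (0.13). Mx1 and Msmo1 kept their calls with the range term, while Tyrobp (-0.79, 0.0793), Ctsb (-0.47, 0.129), Ifit3 (1.91, 0.067), Trim30a (0.62, 0.0757), Sc5d (-0.80, 0.0649) and Insig1 (-1.35, 0.152) lost theirs at similar values. The authors' subcluster 5, named IFN Response, held 3.39%, 5.17% and 1.73% of the microglia of the 3 TauPS2APP mice. It held 3.90%, 16.9% and 33.6% of those of the 3 knockout mice, so knockout mouse 1 lay within the TauPS2APP range. Proliferation had 0 of 9 passing with a median of 1.69 (adjusted p = 0.485 with an estimated correlation). In all 372 of 12660 genes passed, 160 higher and 212 lower. The count was 827 without knockout mouse 1, 90 without TauPS2APP mouse 3, 185 without TauPS2APP mouse 2, 186 and 144 without knockout mice 2 and 3, 100 with only the 6 mice, and 121 with the range term. It was 0 without the cells that hold markers of another class, which keeps 21.0% of microglia, and 1302 without the filter on low genes.

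In astrocytes 4 genes fell without Trem2, namely Trem2 (1 UMI against 85), Cst7 (-3.86), Lyz2 (-2.42) and Tyrobp (-2.42), and all were at 10 or more times the level in microglia. In oligodendrocytes 10 genes fell, all at 10 or more times the level in microglia, including Cst7 (-4.04 ± 0.35, adjusted p = 6.3e-04), Trem2, Spp1, Lpl, Lyz2, Tyrobp and Cd68, of which Cst7, Tyrobp and Lpl kept their calls with the range term. In endothelial cells 5 genes fell, also microglial: Spp1, Trem2, Cst7, Tyrobp and Ctsd. The range term ended the calls of Lyz2 in astrocytes (-2.37, 0.147) and of Spp1 in endothelial cells (2 UMIs against 83, 0.601). Reactive astrocyte genes had 0 of 17 passing (median -0.04, mean 0.12) and astrocyte interferon genes 0 of 7 with 3 higher adjusted over the list alone (median 1.16, or 0.443 to 1.35 with 1 mouse left out, adjusted p = 0.257 with an estimated correlation). Myelin genes had 0 of 18 passing (median -0.17, adjusted p = 0.300 with an estimated correlation), and oligodendrocyte interferon genes 2 higher adjusted over the list alone (median 1.36, or 0.692 to 1.89 with 1 mouse left out, adjusted p = 0.300 with an estimated correlation). The authors' oligodendrocyte cluster 18, led by Igtp, Ifit3 and Ifi27l2a, held 0.960%, 1.86% and 10.4% of the oligodendrocytes of knockout mice 1, 2 and 3. Endothelial inflammation had 0 of 10 passing and 3 lower adjusted over the list alone (median -0.55, or -1.50 to -0.12 with 1 mouse left out, adjusted p = 0.297 with an estimated correlation), and barrier genes 0 of 14 (-0.01). The astrocyte count was 2 without TauPS2APP mouse 2 or 3. The oligodendrocyte count was 5 without either of these mice, 6, 3 and 3 without knockout mice 1, 2 and 3, 33 with DESeq2 and 3 with the range term, and the endothelial count was 3 without TauPS2APP mouse 3.

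TauPS2APP;Trem2ko against Control shows which levels differ from Control without Trem2. By gene, 317 microglial (216 higher), 83 astrocyte (72 higher), 1904 oligodendrocyte (1036 higher) and 7 endothelial genes (3 higher) passed, without named genes or alternatives for these counts. In microglia 12 of 24 late genes rose (22 adjusted over the list alone, median 1.31, 0.0309), 4 of 7 early genes rose, 4 of 14 homeostatic genes fell (median -0.41, 0.0449) and 6 of 18 interferon genes rose (16 adjusted over the list alone, median 1.11, 0.0449). MHC class II rose in 3 of 6 (adjusted p = 0.119 with an estimated correlation), MHC class I in 4 of 12 (adjusted p = 0.102 with an estimated correlation) and immediate early genes in 4 of 15 (0.102). In astrocytes 10 of 17 reactive genes rose (median 1.93, 0.006), 7 of 7 interferon genes (median 2.45, 0.006) and 5 of 7 MHC class I genes (0.0108). In oligodendrocytes 10 of 18 myelin genes fell (11 lower and 1 higher adjusted over the list alone, median -0.52, adjusted p = 0.0906 with an estimated correlation) and 6 of 12 MHC class I genes rose (12 adjusted over the list alone, median 2.22, adjusted p = 0.274 with an estimated correlation). In the same cells 2 of 2 T cell markers rose (median 3.22) and 3 of 6 astrocyte markers fell (median -0.54).

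Astrocytes made up 2.46 ± 0.967% (SD, n = 6) of the cells of mice with amyloid transgenes and 5.64 ± 2.00% (n = 6) of the cells of the other mice (exact permutation p = 0.0108, adjusted p = 0.0433). T cells made up 2.76 ± 0.669% against 1.60 ± 0.915% (exact permutation p = 0.039, adjusted p = 0.0779), and with 1 mouse left out the unadjusted p was above 0.05 in 8 of 12 cases. Microglia made up 21.5 ± 8.38% against 14.8 ± 3.19% (adjusted p = 0.139) and oligodendrocytes 47.8 ± 8.96% against 43.7 ± 7.38% (adjusted p = 0.396). By group, microglia held 16.8% of Control, 12.8% of P301L, 29.0% of TauPS2APP and 13.9% of TauPS2APP;Trem2ko cells, and T cells held 0.907%, 2.30%, 2.35% and 3.18%. The difference for T cells was 2.74 points of immune cells (exact permutation p = 0.387) when only immune cells were counted. Between 2 groups of 3 mice the smallest possible p was 0.1. The cells were sorted, and a sort can set such shares. Neither the shares nor the cluster abundance below was tested with the range of cell numbers as a term. Every mouse of the first range carried the amyloid transgenes, and of the amyloid mice only knockout mouse 3 lay outside it. Differences of shares by amyloid can therefore hardly be told apart from the range. Cluster differences of TauPS2APP against Control or P301L cannot be told apart from it. By the abundance model 2 clusters passed in P301L against Control, both higher (4 passed without Control mouse 1). In TauPS2APP against Control 10 passed, 4 higher and 6 lower, and between 4 and 6 passed when Control mouse 2 or 3 or any 1 TauPS2APP mouse was left out. Among the 10, T cell cluster 12 was higher (log2 1.36, adjusted p = 0.0346) and astrocyte cluster 6 lower (-1.65, adjusted p = 0.0272). In TauPS2APP against P301L 6 passed, 3 higher and 3 lower (3 without TauPS2APP mouse 3), and in the knockout against TauPS2APP 1 passed, lower.

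**Figure D5:**
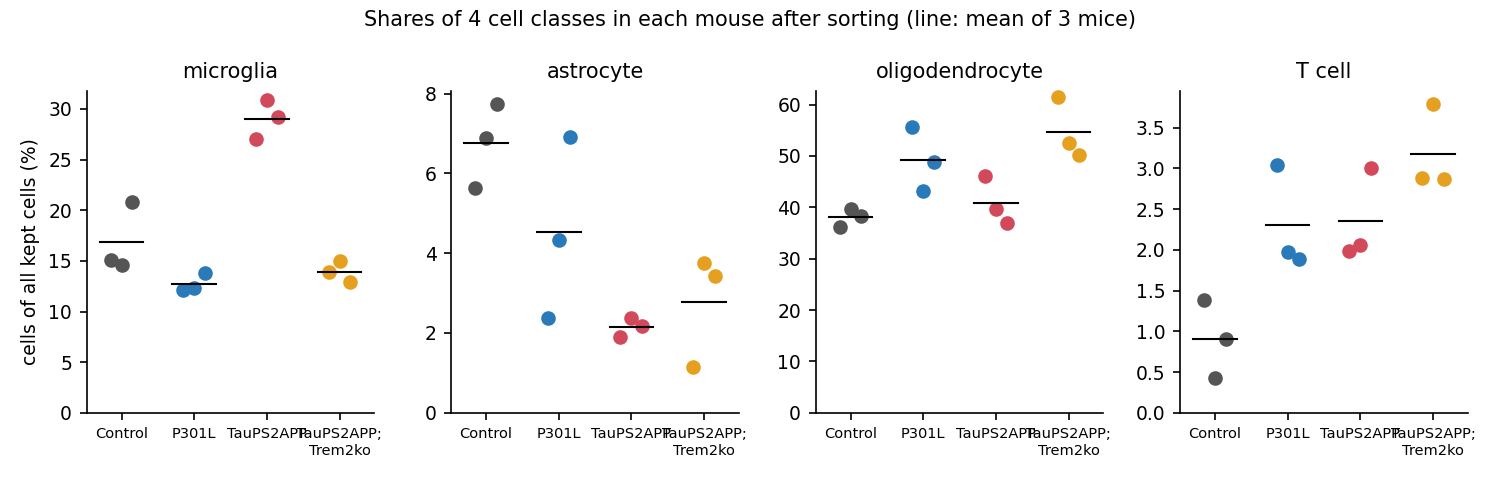
Shares of microglia, astrocytes, oligodendrocytes and T cells among the annotated cells of each mouse.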

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

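The patterns of this part were chosen after they were seen. The tests on swapped sample indexes, on a library outside the series and on the neighbours on chromosome 19 were written after their results were seen, and the others before, although the test on the knockout mouse's own Trem2-expressing microglia replaced an earlier one whose value had been seen.

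A knockout library held Trem2 UMIs. In the library labelled TauPS2APP;Trem2ko 1, 89 of 589 microglia held 3 or more Trem2 UMIs, against 1 and 5 cells in the other 2 mice of the group and 5 in the knockout mouse of the Control group. All 78 of its cells in subcluster 6 were among them, and its other microglia had 7.89 CPM. The 10 leading genes of subcluster 6, named Classically Activated, included Il1b and Cxcl2 and the neutrophil markers S100a8 and S100a9. The positive cells were rich in Apoe (99138 CPM against 16299 in cells without a Trem2 UMI), Spp1 (4374 against 4.47), Il1b (1768 against 9.83), Cxcl2 (1121 against 0.894) and Cd74 (2916 against 38.4), and low in P2ry12 (304 against 1818) and Maf (85.4 against 1069).

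A swap of sample indexes that left copies of these cells in 1 other library of the series is argued against. At most 6.742% of their barcodes occurred in any 1 other library, and 14 of the 89 occurred in at least 1 of them. The number due by chance was not computed. Cells moved whole from another library would share no barcode with it, so the test does not reach that case. Cells from a library outside these 12 could be involved: 4 of 613 genes present in every mouse had 0 UMIs in subcluster 6, with 132 due, but the bound set for this was 5, 1 more than found. The 4 were Rn7sk, Gm5928 and the ribosomal pseudogenes Rps15a-ps6 and Rpl9-ps6. An equally deep part of subcluster 3 of the same mouse lacked 0 of the 613 and held 177, 119, 86 and 109 UMIs of these 4 genes. A Trem2-expressing part of this mouse's own microglia is not excluded. By the test set for it, the summed ribosomal pseudogene level of subcluster 6 was 0.8463 of that of the lowest mouse. The level was 5748 CPM, against 6792 in the microglia of knockout mouse 2, the lowest, and 16402 in the other microglia of this mouse. The 15 subcluster 6 cells of the other mice held 6248 CPM, so a low level was not particular to this mouse. The absence of these 4 genes speaks against a Trem2-expressing part of its own microglia, and the test leaves this explanation open. That last test replaced a first version, based on the count of 4 genes, after that count had been seen. Leaving the positive cells out gave 432 changed genes against TauPS2APP, and leaving out subcluster 6 gave 430, where the report has 372.

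Oligodendrocyte precursors were not part of the comparisons of the report, and 22 of their 12252 tested genes passed in TauPS2APP against Control, 16 of them at 10 or more times the level in microglia. Microglial genes also passed in astrocytes, oligodendrocytes and endothelial cells. Of 249 such calls, 187 (75.1%) moved within 2 SE of the change of their microglial UMIs as a share of all UMIs of the mouse. This was barely past the 75% set for free microglial RNA taken up with other cells, which stays a candidate explanation. A change with a wide SE falls within 2 SE more easily, and the calls repeat genes and mice over the comparisons, so the share cannot decide. In oligodendrocytes of TauPS2APP against Control the part was only 59%. Without cells holding markers of another class, the median change of the 198 calls that could still be fitted was 1.014 times the original, which argues against doublets with microglia in oligodendrocytes, where it was 0.807 times even with the 29 unfitted of 203 calls counted as a change of 0, a bound added after the first value was seen. In astrocytes and endothelial cells, where 10 of 25 and 12 of 21 calls could not be fitted, doublets are left open. An expression of these genes by the other classes was not tested.

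The neighbours Prune2, Gcnt1 and Rfk passed together in P301L microglia. In 2.73% of 10000 draws as many tested genes fell into one 5 Mb window, a value between the bounds set (5% and 1%), and it leaves out that 20 screens of class and comparison were searched. In 8 of 9 combinations of gene and other class (88.89%) all P301L mice lay beyond all Control mice in the microglial direction. For 1 combination alone 5% is due, but the 9 share 3 genes and the same 6 mice and are not independent. An effect of this stretch of the chromosome in every class may explain the pattern. In TauPS2APP mice, which also carry mutant tau, Prune2 stood near Control in astrocytes (34.7 against 30.6 CPM) and oligodendrocytes (27.5 against 24.4). Rfk in TauPS2APP oligodendrocytes did not (63.8 against 32.2). In oligodendrocyte precursors Prune2 stood at 224 CPM in Control, 48.2 in P301L, 135 in TauPS2APP and 110 in TauPS2APP;Trem2ko mice. Whether flanking sequence of another strain or an inserted transgene lies there was not tested.

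The groups were also split in other ways. Of the 10 ways to split 6 mice into 3 and 3, only 1, the real one, gave as many changed genes in 12 of the 16 counts, and 10 splits cannot give a share under 0.05. A split that mixes the groups puts their difference into the spread within groups, which by itself lowers its count. TauPS2APP shares no range of cell numbers with Control or P301L, so an effect of the range could give the same counts there. In microglia the real and the highest other count were 25 and 0, 2208 and 0, 943 and 0, and 372 and 66, in the order P301L against Control, TauPS2APP against Control, TauPS2APP against P301L and knockout against TauPS2APP. In astrocytes they were 3 and 0, 39 and 0, 14 and 1, and 4 and 4.

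In oligodendrocytes these counts were 5 and 0, 1047 and 0, 520 and 0, and 10 and 38, and in endothelial cells 0 and 1, 21 and 2, 9 and 0, and 5 and 20. As many genes passed in 2 splits for the knockout against TauPS2APP in astrocytes, oligodendrocytes and endothelial cells, and in 10 for endothelial cells of P301L against Control. The split of TauPS2APP mice 1 and 2 with knockout mouse 1 from the other 3 gave the 66, 38 and 20, which could reflect a structure of these samples other than the genotype.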

How the results depend on the processing

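Counts of passing genes depended on the mice, on the cells and on the range of cell numbers more than on scaling, and with 3 mice per group and 49 astrocytes in the smallest sample depth limits what can pass. No paired analysis was possible because replicate numbers only name the mice. Of 193 named calls, 188 passed with DESeq2, 191 with RLE scaling, 190 without a filter and 56 with the range term, an alternative chosen after the data were seen in which 134 lost their call and 3 reversed. Of these 137, 111 kept at least 0.667 of their log2 fold change, so most of them were lost without a much smaller change. The term rests on the few mice whose range differs from that of others in their group. Without cells holding markers of another class, which keeps 21.0% of microglia, 94 of 158 passed. RLE scaling and the filter on cells moved no count by over 1.5 times. The cause was not tested for the counts below, apart from the fewer mice, cells or genes that an alternative itself sets. Below, comparison 1 is P301L against Control, 2 is TauPS2APP against Control, 3 is TauPS2APP against P301L and 4 is knockout against TauPS2APP, and only counts that moved are given.

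With DESeq2 microglia had 147 (comparison 1), oligodendrocytes 44, 960 and 33 (1, 3, 4), and endothelial cells 36 and 19 (2, 3). Without a filter microglia had 304, 1763 and 1302 (1, 3, 4), astrocytes 78, 76, 29 and 21, oligodendrocytes 446, 1712 and 270 (1, 3, 4) and endothelial cells 66, 130, 113 and 40. With only the 6 mice compared microglia had 1612 and 100 (3, 4), oligodendrocytes 1, 1292 and 6 (1, 3, 4) and endothelial cells 23 (3). Without cells holding markers of another class microglia had 1, 272, 83 and 0, astrocytes 22 and 8 (1, 2), oligodendrocytes 3, 613, 256 and 6, and endothelial cells 2, 0 and 0 (2 to 4). Thinned counts gave 13 and 613 in microglia (1, 3), 0, 11, 3 and 2 in astrocytes, 3 in oligodendrocytes (1) and 9 in endothelial cells (2). P301L mouse 1 alone, a group of 1 mouse, gave 0 and 29 in microglia (1, 3), 12 and 0 in astrocytes, 2 and 5 in oligodendrocytes and 5 in endothelial cells (1). The range term gave 1, 124, 0 and 121 in microglia, 14, 14 and 1 in astrocytes (1 to 3), 1, 105, 0 and 3 in oligodendrocytes and 1 and 0 in endothelial cells (2, 3). All cells with the authors' name gave 1 in endothelial cells (4). Leaving out genes at 10 times the level in microglia gave 23, 4 and 0 in astrocytes (2 to 4), 0 in oligodendrocytes (4) and 3, 0 and 0 in endothelial cells (2 to 4). The T cell share over immune cells differed by 2.742 points and no longer passed unadjusted.

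With each mouse left out in turn, the lowest and highest counts in the same order were 2 and 80, 1209 and 1897, 310 and 792, and 90 and 827 in microglia. They were 2 and 30, 20 and 36, 5 and 25, and 2 and 6 in astrocytes, 3 and 18, 554 and 757, 166 and 367, and 3 and 11 in oligodendrocytes, and 0 and 5, 5 and 27, 3 and 8, and 3 and 5 in endothelial cells. The T cell share difference ran from 0.9221 to 1.444 points, with an unadjusted p above 0.05 in 8 of 12 cases, that of astrocytes from -3.835 to -2.758, that of microglia from 4.812 to 8.4 and that of oligodendrocytes from 1.434 to 6.566. Of 48 list medians of at least 0.5 in size, 21 moved by over 1.5 times in at least 1 case. Numbers of passing clusters ran from 2 to 4, 4 to 9, 3 to 7 and 1 to 1.

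In some lists the direction of the test with the preset correlation reversed, and their medians there are given here. Without cells holding markers of another class the microglial medians were -0.1451 for interferon genes in P301L against Control (where -0.61 was reported) and 0.2592 for cholesterol synthesis in the knockout against TauPS2APP. The homeostatic astrocyte median was 0.05953 in P301L against Control, and endothelial immediate early genes had 0.02048 in P301L against Control and -0.0756 in TauPS2APP against Control. Immediate early genes of P301L microglia had -0.03996 with P301L mouse 1 alone and -0.02866 with the range term. Those of the knockout against TauPS2APP ran from -0.4227 without knockout mouse 1, where the test reversed, to 0.3774 without knockout mouse 2. Reactive astrocyte genes ran from -0.1656 without knockout mouse 2 to 0.2903 without TauPS2APP mouse 3, and their test reversed at 0.1310 without knockout mouse 1. Astrocyte interferon genes of P301L had -0.03347 without a filter, and homeostatic astrocyte genes 0.06285 when thinned. With the range term oligodendrocyte interferon genes had 0.6794 in TauPS2APP against Control and MHC class I -0.2108 in the knockout against TauPS2APP, which ran from -0.1777 without knockout mouse 3 to 1.321 without knockout mouse 1. Endothelial MHC class I in the knockout against TauPS2APP ran from -0.2334 without TauPS2APP mouse 1 to 0.2299 without TauPS2APP mouse 2, where the test reversed. Of named genes Ctsb in microglia of the knockout against TauPS2APP reversed to 0.1356 without cells holding markers of another class. With the range term Gm49369 reversed in astrocytes of TauPS2APP against Control to -1.433, Trem2 in astrocytes of TauPS2APP against P301L to -0.6696, and Gm49369 in oligodendrocytes of TauPS2APP against P301L to -0.05325.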

Other observations

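The tests of this part were chosen after the results of the report were seen. For precursors and T cells they were run once, without the range term, a left-out mouse or another alternative. In oligodendrocyte precursors, which are not in the report, C4b rose in TauPS2APP mice by 2.70 ± 0.23 over Control (139 ± 8.98 against 20.6 ± 8.29 CPM, adjusted p = 1.8e-05) and in P301L mice by 1.56 ± 0.23 (63.5 CPM, adjusted p = 0.019). The prion protein gene Prnp rose by 1.43 ± 0.13 in TauPS2APP precursors (1235 ± 126 against 459 ± 28.6 CPM, adjusted p = 4.7e-05). In microglia Prnp measured 1.44 ± 0.20 (adjusted p = 3.0e-04), in astrocytes 0.10 ± 0.15 (0.897), in oligodendrocytes -0.16 ± 0.12 (0.536) and in endothelial cells 0.19 ± 0.15 (0.847). Over P301L it measured 1.40 in TauPS2APP microglia (adjusted p = 0.00144), -0.03 in astrocytes, -0.12 in oligodendrocytes and 0.06 in endothelial cells. Aldh1a1, a retinoic acid enzyme gene at 20492715 to 20643465 of chromosome 19 in GRCm38, rose by 2.33 ± 0.27 in P301L precursors (adjusted p = 0.00137), and Prune2 fell by 2.28 ± 0.20 (adjusted p = 4.5e-05). The numbers of passing precursor genes were 3 in P301L against Control, 22 in TauPS2APP against Control, 21 in TauPS2APP against P301L and 5 in the knockout against TauPS2APP, of which 0, 16, 16 and 5 were at 10 or more times the level in microglia. An unadjusted p below 0.05 was found for 478, 533, 624 and 547 precursor genes, where 613 are due by chance.

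T cells had 4417 tested genes, of which 0 passed in any comparison with edgeR, while 187, 216, 351 and 253 had an unadjusted p below 0.05 in the 4 comparisons, where 221 are due by chance. Oligodendrocyte precursors made up 12.6% of Control, 8.83% of P301L, 8.86% of TauPS2APP and 6.92% of TauPS2APP;Trem2ko cells.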
